A study of Mus musculus with 6 samples.

How the data were processed

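Whole testes of mice at postnatal day 4 were compared between 3 samples labelled WT and 3 labelled cKO for Dis3l2, with the strain given as B6D2F1. Per the labels, total RNA was depleted of ribosomal RNA and made into strand-selected libraries with random and poly(T) priming, while the molecule field names polyA RNA, and the labels do not settle the difference. Per the file headers the deposited values are raw counts of reads per gene from featureCounts 1.6.4 on GENCODE M18 gene models, counted on the gene's strand. Reads that mapped to more than 1 place or lay over more than 1 gene were not counted, and reads were not counted as pairs. The authors' notes name cutadapt, HISAT2 and the build GRCm38.p5, with no versions of the tools. The table held 54232 genes, of which 54165 were named and typed from the GENCODE M21 annotation, and 0 columns were left without a sample.

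Totals ranged from 26126694 to 43265614 counts per library. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 20153, and libraries were scaled by TMM. The groups were compared with the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, group as the only term, WT as reference, two-sided) and p-values were adjusted by Benjamini-Hochberg over all genes kept. A gene past the threshold, or called, had an adjusted p under 0.05. Log2 fold changes are cKO over WT, CPM values use the TMM-scaled library sizes, and log2 CPM for scores used a prior count of 2. CPM values of olfactory and other receptor families use the total counts, with exact 95% Poisson intervals that cover counting error only.

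Before the data were examined, 26 gene lists, the tests, the rule for named genes and most alternatives were fixed. Lists with at least 5 genes kept were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 26 lists, and again with an estimated correlation and with fry. The scores were compared with exact two-sided permutation tests, whose smallest p is 0.1 for 3 against 3 samples. Genes within 10 Mb of Dis3l2 were compared with all others by Fisher's exact test. The genes named are Dis3l2, the 12 largest rises and 12 largest falls, and up to 4 members with the lowest p from each list that was past the threshold or had a called member. The largest changes were taken among called genes with a mean of at least 1 CPM and no overlap between groups, without pseudogenes and predicted or unnamed models. The rule gave 113 genes, most of which are given below. Transcripts of the named genes were searched for copies in other gene models with minimap2 2.31-r1302 (at least 95% identity over at least 30% of the transcript), and 11 had a copy.

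The procedure was tested on simulated data with planted changes. In edgeR, 48% of genes planted at a log2 fold change of 0.5 and 66% of those planted at 1 were called, and 8.51% of calls had not been planted. The planted list was found by camera and 0 of the 25 lists without a planted change were called, at the preset correlation. The simulated genes were drawn independently of each other, so this does not test the preset correlation for lists of correlated genes. In the real data the estimated correlation was 0.175 for the general germ cell list. Changes near or below a log2 fold change of 0.5 were thus often missed at this depth and number of samples, and part of those of 1 were missed as well.

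Alternatives were DESeq2 size factors or library size alone as the scaling, no filter or at least 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, the robust fit, the replicate number as a block, each library left out in turn, and mitochondrial, haemoglobin, ribosomal and small RNA genes left out. Others were a minimum absolute log2 fold change of 1, windows of 5 and 20 Mb, a prior count of 0.5 and list medians for the scores. Leaving out chromosome 8, leaving out genes prone to background reads, and a background covariate were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3).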

Results

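RNA was sequenced from whole mouse testes at postnatal day 4, in 3 samples labelled wild type (WT) for Dis3l2 and 3 labelled as conditional knockouts (cKO). Dis3l2 encodes an exoribonuclease that degrades RNAs carrying an oligouridine tail, among them precursors of let-7 microRNAs. At this age the seminiferous cords hold Sertoli cells and the first spermatogonia, and meiosis has not begun. The stated purpose of the series was to find the genes that differ between control and cKO testes, and its title concerns the differentiation of spermatogonia. The WT libraries held 41654998, 43265614 and 35750784 counts and the cKO libraries 26126694, 34708401 and 35390560. The labels do not say whether the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples, part of which may be technical.

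The targeted gene itself did not differ at the level of whole-gene counts. Dis3l2 (chromosome 1, 86703808 to 87050095, GRCm38, plus strand) had 31.95 ± 0.93 CPM (counts scaled by library size) in WT (SD, n = 3) and 31.72 ± 1.65 CPM in cKO (SD, n = 3). The log2 fold change of cKO over WT was -0.01 (SE 0.07, adjusted p = 0.956, edgeR quasi-likelihood test), and it was above 0 without WT replicate 1, cKO replicate 1 or cKO replicate 2. The single values were 32.8, 31.0 and 32.1 CPM in WT and 30.6, 31.0 and 33.6 CPM in cKO. A count over the whole gene includes reads from exons outside a deleted part and from cells in which no deletion took place, and reads that also lie in 1 of the predicted gene models inside the gene were not counted. The labels name neither the deleted exons nor the Cre driver. The counts therefore do not check the genotype labels, and "cKO" below stands for the libraries labelled so.

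Germ cell transcripts were lower in the cKO testes. Of the 30 general germ cell genes, all measured, 24 fell, 0 rose and 6 did not pass the test, and 29 were lower when adjusted over the list alone. The list's median log2 fold change was -0.76, and all 30 members had fitted values below 0. Tex15, needed for silencing of retrotransposons in male germ cells, fell from 290.8 ± 9.2 to 125.4 ± 4.6 CPM (SD, n = 3 each; log2 fold change -1.21, SE 0.05, edgeR adjusted p = 7.8e-08), and it lies on chromosome 8 between 30 and 95 Mb, where called genes were in excess. Ddx4, the germ cell RNA helicase also known as Vasa, fell from 110.1 ± 5.2 to 53.2 ± 2.6 CPM (SD, n = 3 each; log2 fold change -1.05, SE 0.06, edgeR adjusted p = 9.7e-07). The Tudor domain gene Stk31 (-1.03) and the mRNA export gene Nxf2 (-0.86) fell as well. The general germ cell list was past the threshold in camera (adjusted p = 5.3e-26 with the preset correlation). With an estimated correlation it was not (adjusted p = 0.151). In each library the mean log2 CPM of the germ cell list minus that of the Sertoli cell list was taken as a score, which was -1.44 ± 0.08 in WT and -2.28 ± 0.05 in cKO (SD, n = 3 each). The difference of -0.84 had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples allow.

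Both classes of spermatogonial genes contained genes that fell. Among 30 undifferentiated spermatogonia and stem cell genes, 11 fell, 1 rose and 18 did not pass, with a median log2 fold change of -0.27. Adjusted over the list alone, 12 were lower and 2 higher. The transcription factor gene Zbtb16, also called Plzf and required for stem cell maintenance, fell from 79.9 ± 3.5 to 45.9 ± 3.8 CPM (SD, n = 3 each; log2 fold change -0.80, SE 0.07, edgeR adjusted p = 3.8e-05). Ret, which encodes the signalling receptor for GDNF, fell by 0.82 on the log2 scale, Cdh1 (E-cadherin) by 0.73 and Id4 by 0.59. The 1 member that rose was Pax7 (log2 fold change 0.83), named after its values were seen because it was the only higher call of the list. The list's camera adjusted p was 2.1e-05, and the adjusted p was 0.268 with an estimated correlation.

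Of the spermatogonial differentiation genes, 15 were measured, of which 8 fell, 0 rose and 7 did not pass, with the same 8 and 0 when adjusted over the list alone. The median log2 fold change was -0.38 (camera adjusted p = 2.1e-05, and adjusted p = 0.189 with an estimated correlation). With the background covariate, chosen after the data were seen, it was -0.57. Stra8, a retinoic acid target that marks spermatogonia entering differentiation, fell from 31.2 ± 0.6 to 16.1 ± 0.7 CPM (SD, n = 3 each; log2 fold change -0.95, SE 0.08, edgeR adjusted p = 1.7e-05). The X-linked homeobox genes Rhox10 (-1.44) and Rhox13 (-0.92) and the transcription factor gene Sohlh1 (-1.02) fell in the same test. The mean log2 CPM of the differentiation list minus that of the undifferentiated list was 0.045 ± 0.067 in WT and -0.185 ± 0.013 in cKO (SD, n = 3 each). The 3 cKO libraries lay below the 3 WT libraries, and the difference of -0.23 had an exact two-sided permutation p of 0.1, the smallest possible. With the median of each list in place of the mean, the difference was -0.17 and the exact two-sided permutation p was 0.6. In whole testes the score does not separate a change in the balance of these cells from a loss of germ cells that moves the lists unequally.

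Genes known for meiotic prophase were already measurable, and some were lower in cKO. Of 28 measured, 8 fell, 0 rose and 20 did not pass, and 15 were lower and 1 higher when adjusted over the list alone. The median log2 fold change was -0.39 (camera adjusted p = 1.2e-07, and adjusted p = 0.151 with an estimated correlation). The synaptonemal complex genes Tex12 (-0.83), Syce1 (-0.77) and Sycp1 (-0.39) and the crossover gene Tex11 (-0.75) fell.

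**Figure D1:**
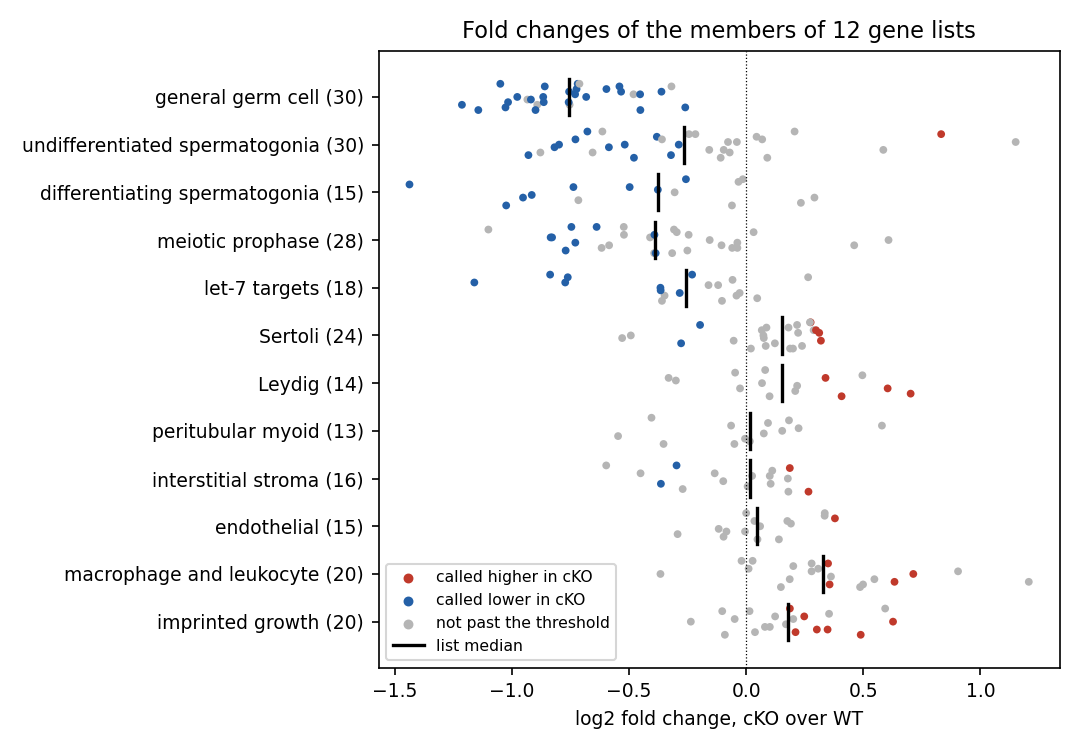
Log2 fold change of cKO over WT (horizontal axis) for each measured member of 12 gene lists, with the number of members in brackets. Red and blue points are genes past the threshold (edgeR adjusted p under 0.05), grey points are not, and black bars are list medians. The general germ cell list lies lowest, with a median of -0.76, and the macrophage and leukocyte list highest, with a median of 0.33.

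**Figure D2:**
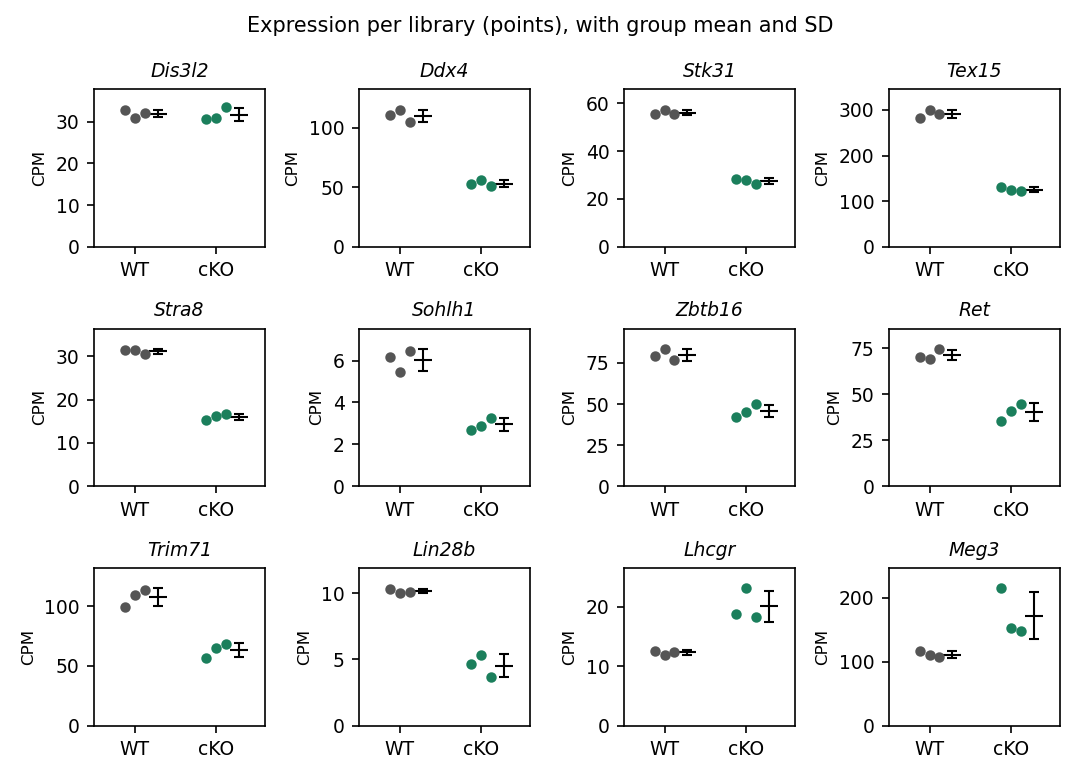
CPM (vertical axes, from 0) of 12 genes in the 3 WT and 3 cKO libraries. Points are libraries, and the bar beside them is the group mean with its SD. Dis3l2 overlaps between the groups, while each of the other genes has no overlap between WT and cKO.

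Some let-7 targets fell, beside the general germ cell list with its median of -0.76. Counts from whole testes cannot tell an effect of let-7 from the fall of germ cell transcripts. Of the 18 let-7 target genes, all measured, 8 fell, 0 rose and 10 did not pass, and 10 were lower when adjusted over the list alone. Lin28b, which encodes an RNA-binding protein that blocks let-7 maturation, fell from 10.1 ± 0.1 to 4.54 ± 0.85 CPM (SD, n = 3 each; log2 fold change -1.16, SE 0.14, edgeR adjusted p = 0.00047). Trim71, which encodes a stem cell ubiquitin ligase, fell by 0.76 on the log2 scale, the nuclear receptor gene Nr6a1 by 0.84 and Arid3b by 0.77. The list, which shares Lin28a with the undifferentiated spermatogonia list, had a median of -0.26 (camera adjusted p = 2.1e-05, and adjusted p = 0.151 with an estimated correlation). Among 29 measured genes of RNA decay and uridylation, 2 fell, 0 rose and 27 did not pass. Adjusted over the list alone, 4 were lower and 1 higher. Those past the threshold were Lin28b, which both lists hold, and Mtrex, the helicase that feeds the nuclear exosome (-0.34). Eri1 (-0.20, edgeR adjusted p = 0.0586) and Exosc4 (0.28, edgeR adjusted p = 0.0512) lay just outside it. Eri1, which lies in the chromosome 8 segment, passed without cKO replicate 1 (edgeR adjusted p = 0.011), in DESeq2 (0.0353), with a stricter filter on low counts (at least 1 CPM in 3 samples, 0.0482) and with library size alone as the scaling (0.0408). Exosc4 passed in DESeq2 (0.0307), limma-voom (0.0493), the robust fit (0.0472) and with the stricter filter (0.042), and DESeq2 called 6 genes of the list in all. This list's median was -0.11 (camera adjusted p = 0.0118, and adjusted p = 0.211 with an estimated correlation). Of 10 measured small structured RNAs described as DIS3L2 substrates, 0 passed the test in edgeR, 0 had an unadjusted p under 0.05, 0 passed in DESeq2 or limma-voom, and 0 passed when adjusted over the list alone. Their median was 0.06 (camera adjusted p = 0.891) and ran from -0.05 without cKO replicate 2 to 0.17 without WT replicate 1, so its sign is not settled. Only 10 of the 20 listed RNAs could be tested, and reads that mapped to more than 1 place were not counted. The shorter RNAs among them may also be poorly represented in such libraries.

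Of 20 measured imprinted and fetal growth genes, 7 rose, 0 fell and 13 did not pass, and 10 were higher when adjusted over the list alone. The median log2 fold change was 0.18 (camera adjusted p = 0.0016, and adjusted p = 0.151 with an estimated correlation). The non-coding RNA Meg3 rose from 111.4 ± 5.3 to 172.3 ± 37.1 CPM (SD, n = 3 each; log2 fold change 0.63, SE 0.11, edgeR adjusted p = 0.0055). Nnat (0.49), the growth factor gene Igf2 (0.30) and Mest (0.21) rose too. The call of Igf2 was lost without WT replicate 2 (edgeR adjusted p = 0.0849) or WT replicate 3 (0.0503). Mest lost its call without WT replicate 1, 2 or 3 or cKO replicate 2, with the highest adjusted p of 0.104 without WT replicate 2. Igf2 shares transcript sequence with a predicted gene model that overlaps it on the same strand, and reads over both were not counted.

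Of 20 measured macrophage and leukocyte markers 4 rose, 0 fell and 16 did not pass. Adjusted over the list alone, 7 were higher. The median log2 fold change was 0.33 (camera adjusted p = 0.00011, and adjusted p = 0.151 with an estimated correlation). The leukocyte surface phosphatase Ptprc (CD45) rose by 0.71 on the log2 scale, the lysozyme gene Lyz2 by 0.63, the growth factor receptor gene Csf1r by 0.36 and the mannose receptor gene Mrc1 by 0.35. All 4 calls were lost without WT replicate 2, with edgeR adjusted p of 0.0748, 0.0997, 0.204 and 0.0806. Some were also lost without WT replicates 1 or 3 or cKO replicates 2 or 3, the highest adjusted p there being 0.193 for Csf1r without WT replicate 1, and Csf1r also with library size alone (0.0551). Lyz2 has a near-identical copy, Lyz1, so that part of its reads may not have been counted.

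Markers of the supporting cells included genes that rose. Of 24 Sertoli cell markers, 4 rose, 2 fell and 18 did not pass, and 5 were higher and 2 lower when adjusted over the list alone. The median was 0.15 (camera adjusted p = 0.0408, and adjusted p = 0.714 with an estimated correlation). Gdnf, the niche factor for spermatogonial stem cells, rose by 0.30 on the log2 scale, Cst12 by 0.31 and Clu (clusterin) by 0.28, and Kitl, the ligand of the KIT receptor on differentiating spermatogonia, fell by 0.28. Kitl lost its call without WT replicate 2 (edgeR adjusted p = 0.0579). Gdnf lost it without any of the WT replicates or cKO replicate 2 (0.0787, 0.0903, 0.0768 and 0.109). Clu lost it without WT replicate 1 or 3 or cKO replicate 2 (0.0619, 0.0532 and 0.062), and Cst12 without WT replicate 1 or cKO replicate 2 (0.0604 and 0.0649). In fry the Sertoli list did not pass (adjusted p = 0.296). In camera it was no longer past the threshold without WT replicate 1 or 3 or cKO replicate 2 or 3 (camera adjusted p = 0.0668, 0.117, 0.196 and 0.154), and its median was 0.10 without cKO replicate 3.

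Of 14 measured Leydig cell markers, 4 rose, 0 fell and 10 did not pass, and 6 were higher when adjusted over the list alone. The luteinizing hormone receptor gene Lhcgr rose from 12.4 ± 0.4 to 20.1 ± 2.7 CPM (SD, n = 3 each; log2 fold change 0.70, SE 0.11, edgeR adjusted p = 0.0017). The steroid 17-alpha-hydroxylase gene Cyp17a1 rose by 0.60 on the log2 scale, Scarb1, a lipoprotein receptor, by 0.41, and Star, which carries cholesterol into mitochondria, by 0.34. The median was 0.15 (camera adjusted p = 0.0408, and adjusted p = 0.225 with an estimated correlation). The list call was lost without WT replicate 1, 2 or 3 or cKO replicate 3 (camera adjusted p = 0.0791, 0.0502, 0.0624 and 0.104) and with the replicate number as a block (0.0546) or without the genes of chromosome 8 (0.0933), an alternative chosen after the data were seen. Scarb1 alone had overlapping groups, and its call was lost without any single library other than cKO replicate 1, with edgeR adjusted p between 0.119 and 0.213, and in the robust fit (0.175). The list median was 0.09 without cKO replicate 3.

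Other cell type lists showed smaller changes or fewer calls. Among 16 interstitial stroma genes 2 rose, among them Fn1 (0.19), and 2 fell (the collagen genes Col1a2, -0.36, and Col3a1, -0.30), and 4 and 3 did when adjusted over the list alone. The stroma median was 0.02 and the mean -0.07, of the opposite sign (camera adjusted p = 0.783). Of 15 endothelial markers Pecam1 rose (0.38) and 14 did not pass, among them Eng (0.19), Cdh5 (0.14) and Erg (-0.29). Cdh5 and Eng passed without cKO replicate 1 (edgeR adjusted p = 0.0034 and 0.007). The endothelial count was 1 and 0 when adjusted over the list alone (median 0.05, camera adjusted p = 0.354). Of 13 peritubular myoid markers 0 passed in edgeR, 0 in DESeq2 and 0 in limma-voom, 3 had an unadjusted p under 0.05 in edgeR, and 0 passed when adjusted over the list alone (median 0.02, mean -0.0077, camera adjusted p = 0.783). Of 7 measured red blood cell genes 0 passed in edgeR, 0 in DESeq2 and 0 in limma-voom, 1 had an unadjusted p under 0.05 in edgeR, and 0 passed when adjusted over the list alone (median 0.03, camera adjusted p = 0.650). Without WT replicate 1 the red blood cell list passed (camera adjusted p = 0.0406, median 0.34), while its median was -0.12, -0.06 and -0.07 without WT replicate 2, WT replicate 3 and cKO replicate 1. Of 6 measured fat tissue markers Cidea rose (0.43), with Retn (1.35), Fabp4 (-0.38) and Plin1 (0.12) not past the threshold, and 1 was higher when adjusted over the list alone (median -0.0029, mean 0.12, camera adjusted p = 0.575). With single libraries left out, the medians ran from -0.07 to 0.05 for stroma, from 0.03 to 0.13 for endothelial, from -0.15 to 0.08 for myoid and from -0.10 to 0.16 for fat tissue genes. The lowest stroma and myoid values came without cKO replicate 1 (camera adjusted p = 0.205 and 0.0687), and without the genes of chromosome 8, an alternative chosen after the data were seen, the fat tissue median was -0.13. Without WT replicate 2, edgeR adjusted p was 0.0977 for Fn1, 0.124 for Col1a2, 0.0948 for Col3a1, 0.0649 for Pecam1 and 0.0918 for Cidea. Cidea, Col1a2 and Col3a1 also lost their calls without each other library but cKO replicate 1, and Fn1 without WT replicate 3 or cKO replicate 2. The robust fit ended the calls of Col1a2 (0.117) and Col3a1 (0.0695), and the stricter filter that of Col3a1 (0.0521).

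Of 13 measured epithelial markers of the excurrent ducts 2 fell, 0 rose and 11 did not pass, with the same 2 when adjusted over the list alone. The median was -0.40 (camera adjusted p = 0.0408, and adjusted p = 0.400 with an estimated correlation). The genes that fell were Epcam (-0.45), which encodes an epithelial adhesion protein that spermatogonia also express, and the keratin gene Krt7 (-1.47). Krt19 (-0.79) and Wfdc2 (-0.74) did not pass, and Krt19 passed without cKO replicate 3 (edgeR adjusted p = 0.0413) and with no filter on low counts (0.003). Without WT replicate 1 or cKO replicate 3 the list was not past the threshold (camera adjusted p = 0.247 and 0.0719, medians -0.11 and -0.24), nor with library size alone as the scaling (0.0601) or a stricter filter on low counts (0.0698), nor in fry (0.0842). Krt7 lost its call without WT replicate 1, 2 or 3 or cKO replicate 2 (edgeR adjusted p = 0.140, 0.132, 0.0541 and 0.124).

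Of 30 cell cycle genes 4 fell, 0 rose and 26 did not pass, and 6 were lower when adjusted over the list alone. The replication helicase genes Mcm6 (-0.39) and Mcm4 (-0.20) and the cyclin genes Ccnb1 (-0.40) and Ccna2 (-0.17) fell. The median was -0.09 (camera adjusted p = 0.0014, and adjusted p = 0.400 with an estimated correlation), and in fry the list did not pass (adjusted p = 0.0525). Mcm4 lost its call without any WT library or cKO replicate 3 (edgeR adjusted p between 0.0785 and 0.170), Ccna2 without any single library but cKO replicate 1 (0.066 to 0.213) and with no filter on low counts (0.0856), and Ccnb1 without WT replicate 3 (0.0537). Ccnb1 has 3 near-identical pseudogene copies in the annotation.

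Of 24 measured mitochondrially encoded genes 4 rose, 0 fell and 20 did not pass, and 10 were higher when adjusted over the list alone. The ribosomal RNA mt-Rnr1 rose by 0.34 on the log2 scale, mt-Nd6 by 0.34, mt-Nd5 by 0.30 and mt-Nd2 by 0.28. The share of all counts from the mitochondrial genome was 2.58%, 2.86% and 2.81% in WT and 3.34%, 3.10% and 2.90% in cKO. The median was 0.19 (camera adjusted p = 0.0137, and adjusted p = 0.714 with an estimated correlation). The list call was lost without WT replicate 1 (camera adjusted p = 0.163) or cKO replicate 1 (0.44), where the median was 0.06, and in fry (adjusted p = 0.306). The calls of mt-Nd2, mt-Nd5 and mt-Nd6 were lost without WT replicate 1 (edgeR adjusted p = 0.101, 0.0855 and 0.160), WT replicate 2 or cKO replicate 2, and those of mt-Nd2 and mt-Nd6 without WT replicate 3. The robust fit also ended that of mt-Nd6 (0.0638). Nuclear copies of mt-Nd2 and mt-Nd5 sequence exist in the annotation.

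Replication-dependent histone genes had 5 members lower, 0 higher and 60 not passing among 65 measured, with the same 5 when adjusted over the list alone and a median of -0.11 (camera adjusted p = 0.0539). Hist1h2al, annotated as a processed pseudogene, had 50.5 ± 6.9 CPM in WT and 0.563 ± 0.085 CPM in cKO (SD, n = 3 each; log2 fold change -6.47, SE 0.16, edgeR adjusted p = 3.7e-10). It has 6 near-identical copies and Hist1h2bj (-0.78) has 14, so their counts are uncertain. Hist1h1a fell by 0.23 and Hist1h2aa by 0.34 on the log2 scale, calls lost without WT replicate 1 (edgeR adjusted p = 0.0985 and 0.0705), WT replicate 2 or cKO replicate 2, and for Hist1h2aa WT replicate 3. Without WT replicate 1 or cKO replicate 2 or 3 the histone list passed (camera adjusted p = 0.0406, 0.0319 and 1.7e-05), and its median was -0.29 without cKO replicate 3 and 0.08, of the opposite sign, without cKO replicate 1. It also passed with no filter on low counts (0.0461) and with the background covariate (4.9e-05, median -0.24), the latter chosen after the data were seen.

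Among 77 cytosolic ribosomal protein genes 4 rose, 4 fell and 69 did not pass, and 6 and 4 did when adjusted over the list alone. The median was 0.05, or 0.03 to 0.06 with single libraries left out, and the mean -0.02 (camera adjusted p = 0.373). Rpl29 had 45.3 ± 2.0 CPM in WT and 2.71 ± 0.50 CPM in cKO (SD, n = 3 each; log2 fold change -4.04, SE 0.12, edgeR adjusted p = 1.5e-09), and 33 other gene models hold near-identical sequence, so this count is uncertain. Rps15a fell by 0.38 on the log2 scale and Rpl30 rose by 0.31. Rpl30 lost its call without WT replicate 2 (edgeR adjusted p = 0.0618).

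The remaining lists held few calls. Of 18 measured retinoic acid genes 3 fell, the germ cell genes Stra8, Crabp1 (-0.74) and Rec8 (-0.84), and 15 did not pass, with 3 lower when adjusted over the list alone. That list's median was 0.10 (camera adjusted p = 0.858, direction higher), while fry gave the lower direction. Of 21 interferon-stimulated genes 3 fell, Bst2 (-1.84), Oasl2 (-0.55) and Parp14 (-0.37), and 18 did not pass, including Ifi27 (0.17), with 3 lower and 1 higher when adjusted over the list alone (median -0.04, camera adjusted p = 0.0581). The interferon list passed in fry (adjusted p = 0.0047) and, with no filter on low counts, in camera (0.0262). Its median was -0.11 without WT replicate 2 or cKO replicate 1 or 3, and -0.07 and -0.08 without WT replicates 1 and 3. Bst2 lies in the chromosome 8 segment. Without the genes of chromosome 8, an alternative chosen after the data were seen, the list's camera adjusted p was 0.177. Of 25 p53 and apoptosis genes Gdf15 (0.81) and Polk (0.26) rose and Trp53inp1 (-0.31) fell, Gdf15 lying in the chromosome 8 segment, with Tnfrsf10b (-0.28) among the 22 that did not pass, and 2 were higher and 4 lower when adjusted over the list alone (median 0.02, camera adjusted p = 0.706). Of 24 stress response genes Vldlr rose (0.30), and Creld2 (-0.24), Hsp90b1 (0.11) and Dnajb9 (-0.16) did not pass. Creld2 passed in DESeq2 (adjusted p = 0.0315), in the robust fit (0.0497), with the stricter filter (0.0387) and with library size alone (0.0318). Adjusted over the list alone, 0 stress response genes passed (median 0.05, camera adjusted p = 0.706). Of 16 immediate early genes Klf4 rose (0.29) and Egr2 fell (-0.50), with Hspa1b (0.32) and Ier2 (-0.30) not past the threshold, and 1 and 1 passed when adjusted over the list alone (median 0.02, mean -0.02, camera adjusted p = 0.861). Without WT replicate 1, edgeR adjusted p was 0.183 for Rec8, 0.136 for Parp14, 0.0571 for Gdf15, 0.1 for Polk, 0.122 for Trp53inp1, 0.114 for Vldlr, 0.0642 for Klf4 and 0.0506 for Egr2. These calls were also lost without cKO replicate 2 and, for all but Gdf15, without 1 or more of the other libraries. Crabp1 lost its call without WT replicate 2 (0.0529). With library size alone Polk (0.0521) and Vldlr (0.0558) lost their calls and Tnfrsf10b passed (0.0469). With no filter on low counts Polk lost its call (0.0646) and Hspa1b passed (0.0351), as it did in DESeq2 (0.0391). Hspa1b has a near-identical copy, Hspa1a, so that part of its reads may not have been counted. Vldlr lost its call with the replicate block (0.0572). Without cKO replicate 1, edgeR adjusted p was 0.0265 for Ifi27, 0.0228 for Dnajb9 and 0.0028 for Hspa1b, and the interferon list passed (camera adjusted p = 0.043). With single libraries left out, the medians ran from 0.06 to 0.14 for retinoic acid, from 0.0047 to 0.05 for p53 and apoptosis, from 0.02 to 0.06 for stress response and from -0.03 to 0.09 for immediate early genes. With library size alone the p53 and apoptosis median was -0.0016.

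The largest rises outside the lists were of genes at low or moderate levels. Zic1, a zinc finger transcription factor gene, rose from 1.77 ± 0.35 to 12.4 ± 0.1 CPM (SD, n = 3 each; log2 fold change 2.80, SE 0.15, edgeR adjusted p = 5.1e-07). Gdpd3, a phosphodiesterase gene, rose by 2.71 on the log2 scale, Zfp963 by 2.48, the carbohydrate kinase gene Fggy by 2.06 and Ptprv by 2.04. The chemokine gene Ccl17 rose by 1.96, from 9.56 ± 0.80 to 37.2 ± 1.3 CPM (SD, n = 3 each). Ccdc194 (1.92), Nat8f4 (1.84), the neutrophil alarmin genes S100a9 (1.69) and S100a8 (1.62), the olfactory marker gene Omp (1.66) and the homeobox gene Hoxb8 (1.66) completed the 12. Omp lies within Capn5 on the same strand, and reads over both were not counted.

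The largest falls reached further. Tktl2, a transketolase-like gene, fell from 8.0 ± 1.1 to 0.447 ± 0.111 CPM (SD, n = 3 each; log2 fold change -4.17, SE 0.22, edgeR adjusted p = 4.6e-07), and Rpl29 followed with -4.04. The relaxin receptor gene Rxfp1 fell by 3.34 on the log2 scale, Spp1 (osteopontin) by 2.99 and Ppp1r3b, a glycogen-targeting phosphatase subunit gene, by 2.95. Lpl, which encodes lipoprotein lipase, fell from 178.3 ± 0.9 to 29.5 ± 0.9 CPM (SD, n = 3 each; log2 fold change -2.60, SE 0.06, edgeR adjusted p = 1.2e-10). Serpina3a (-2.17), the germ cell gene Nlrp14 (-1.97), the non-coding RNA Platr28 (-1.92), Bst2 (-1.84), Lipo3 (-1.72), which overlaps Lipo2 and Lipo4 on its strand, and the meiotic helicase gene Hfm1 (-1.70) completed the 12. Hfm1 lost its call without WT replicate 2 (edgeR adjusted p = 0.0538). Of these 24 genes, Zfp963, Ccl17, Ccdc194, Tktl2, Ppp1r3b, Lpl and Bst2 lie on chromosome 8 between 30 and 95 Mb, a segment bounded after the data were seen, with 104 of 507 genes called (20.5%) against 8.03% elsewhere. Nlrp14 and Platr28 lie on chromosome 7 between 100 and 110 Mb, where 22 of 110 genes were called (20%, one-sided Fisher's exact test adjusted p = 0.0122 over 257 windows of 10 Mb). Tex12, Crabp1 and Arid3b lie on chromosome 9 between 50 and 60 Mb, where 24 of 137 were called (adjusted p = 0.0242). Cst12 and Vldlr lie in windows of chromosomes 2 and 19 that also passed (adjusted p = 0.0311 and 0.0468).

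**Figure D3:**
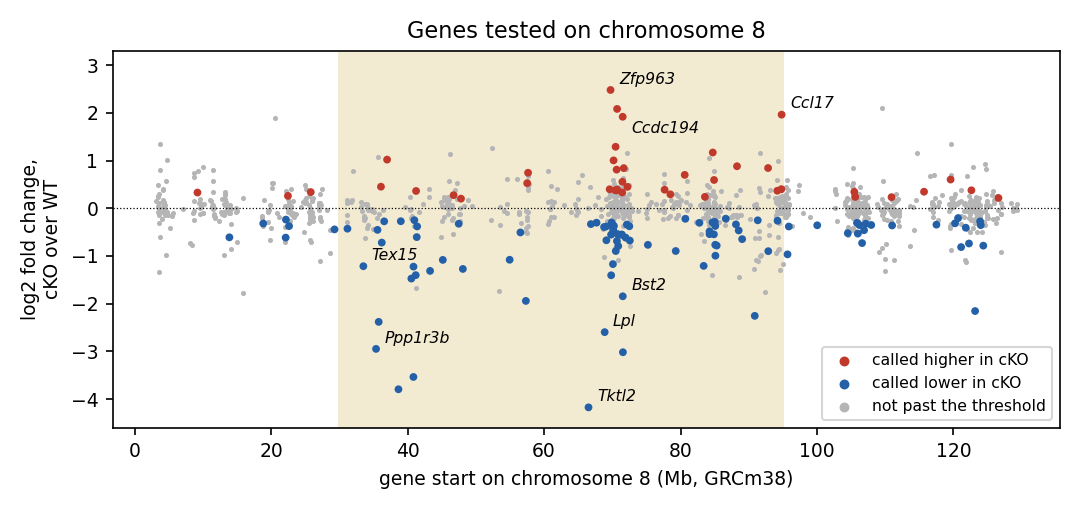
Log2 fold change of cKO over WT (vertical axis) of the genes tested on chromosome 8 against gene start (horizontal axis, Mb, GRCm38). Red and blue points are genes past the threshold, grey points are not, and the shaded segment runs from 30 to 95 Mb, where 104 of 507 genes were past the threshold, 32 higher and 72 lower.

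Over all genes, 1681 of 20153 tested (8.34%) were past the threshold, 685 higher and 996 lower in cKO (edgeR quasi-likelihood test, adjusted p under 0.05), and 4699 had an unadjusted p under 0.05. Most changes were small: the median absolute log2 fold change of called genes was 0.41, 59.9% were under 0.5, and 92 higher and 122 lower genes reached 1. In 1680 of the 1681 called genes the groups did not overlap, as in 28.2% of all tested genes, against 10% by chance for 3 against 3 samples. The first principal component (34.1% of the variance of log2 CPM) separated WT from cKO, and the second (24.7%) set cKO replicate 1 apart from the other libraries. The number of called genes depended on single libraries. It was 759, 623 and 837 without WT replicates 1, 2 and 3, 3375 and 801 without cKO replicates 1 and 2, and 1475 without cKO replicate 3. cKO replicate 1 also held more reads at olfactory receptor genes, which are silent in most tissues, with 212.9 CPM against 97.8, 82.9 and 81.8 CPM in WT and 38.7 and 33.9 CPM in the other cKO libraries. Of the 26 gene lists, 13 were past the threshold in camera with the preset correlation, 8 lower and 5 higher, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05, and 10 with fry.

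**Figure D4:**
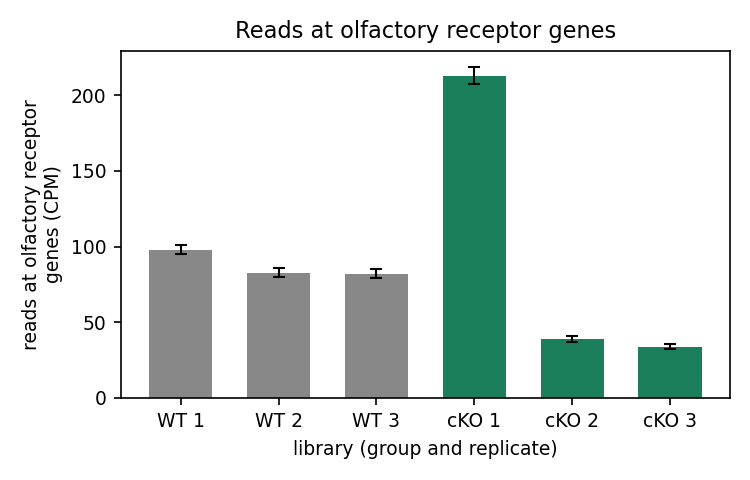
Reads at 1407 olfactory receptor genes per library, in CPM (vertical axis, from 0). Grey bars are WT and green bars cKO libraries, and error bars are exact 95% Poisson intervals, which cover counting error only. cKO replicate 1 reaches 212.9 CPM, above the other 5 libraries, which lie between 33.9 and 97.8 CPM.

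Genes next to the targeted locus were examined because a targeted allele can carry flanking sequence of its founder strain. Within 10 Mb of Dis3l2 on chromosome 1, 10 of 158 tested genes (6.33%) were past the threshold, against 1671 of 19994 (8.36%) elsewhere. The odds ratio was 0.741 (95% interval 0.347 to 1.40, two-sided Fisher's exact test p = 0.469), so that no excess was detected there. In the same exact test the odds ratio was 1.35 without WT replicate 1 (exact p = 0.399) and 1.05 without WT replicate 3 (exact p = 0.842).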

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

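The tests of a common fall of germ cell transcripts and of the share of chromosome 8 in that fall, the bounds of the chromosome 8 segment, and the fit with a background covariate were chosen after the results were seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1681 genes and the highest other split 0. The real split called 13 gene lists with the preset correlation and the highest other split 10. For both counts 1 split, the real one, reached the real value. The odds ratio near Dis3l2 has no such count, since the other splits called 0 genes.

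Reads at olfactory receptor genes drew attention because they lie outside the main measurement and 1 library stood above the WT libraries. cKO replicate 1 had 212.9 CPM (95% Poisson interval 207 to 219) at 1407 such genes, against 97.8, 82.9 and 81.8 CPM in WT and 38.7 and 33.9 CPM in the other cKO libraries. Sequencing depth was argued against for the difference from the other cKO libraries: after thinning to equal depth, cKO replicate 1 had reads at 2.74 times as many of these genes as the higher of them, past the bound of 1.5 set beforehand. The bound against depth named only the other cKO libraries. For WT the ratio was 1.46 to the highest library (1069 genes against 730, 729 and 716), under 1.5. Depth was argued against there by the reads themselves. cKO replicate 1 was the smallest library (26126694 counts), yet it held 5562 reads at these genes, against 4073, 3585 and 2926 in WT. Its ratio to WT was 2.43 for olfactory and 2.24 and 1.95 for the vomeronasal families, at most a factor of 1.24 apart, which reads from genomic DNA or other background would give. The taste receptors, which were to lie within 1.5 times of the olfactory ratio as well, did not, at 1.34 (95% interval 0.992 to 1.78). Background therefore stays open, and no biological explanation was tested. The 16 trace amine receptors had a ratio of 3.96, with a 95% interval of 1.99 to 7.80 that holds the olfactory ratio. Of 782 tested genes with over 20% expected background, 7 were called.

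Of the 30 general germ cell genes 24 were called lower in cKO and 6 did not pass, and all 30 had fitted values below 0. Only Tex15 lies on chromosome 8, so the median of -0.75 over the other 29 members could hardly differ from that of the list and tests nothing, and a location there concerns that gene alone. Background reads, whatever their source, were argued against, since the median was -0.69 without cKO replicate 1 and -0.82 with the background rate as a covariate. Fewer germ cells per testis may contribute. The members' fold changes, from Hells at -0.26 to Tex15 at -1.21, had a spread of 0.264 on the log2 scale beyond their standard errors. A single common fall would leave little spread. In whole testes, however, a member also expressed in other cells would fall less when germ cells are lost. The spread therefore does not tell cell loss from changes within germ cells, and a mixture of both stays open. The genotype named by the design stays open, untested apart from the labels.

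Between 30 and 95 Mb of chromosome 8, 104 of 507 genes were called (20.5%) against 8.03% elsewhere (odds ratio 2.96, 95% interval 2.35 to 3.70, two-sided Fisher's exact test p = 5.5e-18, with bounds drawn from the same data), and of 257 windows of 10 Mb over the genome 10 passed, 5 of them on this chromosome and the others on chromosomes 2, 6, 7, 9 and 19. A gained or lost copy of the segment was argued against by a median log2 fold change of -0.027. Germ cell genes that lie there would add genes called lower, since that list fell. The odds ratio for genes called higher was 1.96 (95% interval 1.31 to 2.83). The bound set beforehand was a ratio under 1.5 for this source and an interval above 1.5 against it, so it decided neither way. An excess of genes called higher argues against germ cell genes as the only source, within a segment drawn from the same data. Their part in the 72 genes called lower stays open. Alleles of different strain origin may also be a candidate source: the bound set beforehand against them was an odds ratio under 1.5 in any fit without 1 library, and the lowest was 1.45, without cKO replicate 1, with an interval of 1.08 to 1.92 that holds the bound. The comparison was first read as excluding them and was changed to take the interval into account after that value was seen. The segment was also drawn from the same libraries that these fits reuse. The ratios therefore cannot decide for or against such alleles.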

How the results depend on the processing

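The alternatives without chromosome 8, without genes prone to background and with a background covariate were chosen after the data were seen. Leaving out 1 library gave 623 to 3375 called genes, 236 to 1670 higher and 387 to 1705 lower, and 61 to 94 of the named genes, against 1681, 685, 996 and 94. The lowest counts came without WT replicate 2 and the highest without cKO replicate 1, where 1665 of the 1681 genes were shared, and fewer samples are part of the lower counts while the cause of the higher one was not tested. A minimum absolute log2 fold change of 1 left 214 genes, 92 higher and 122 lower, by its construction. With an estimated correlation 0 lists passed, and the cause was not tested. The background covariate gave 3555 genes, 1522 higher and 2033 lower, and the cause was not tested. Other settings gave 1484 to 2137 genes, and DESeq2 shared 1630 and limma-voom 1652 of the calls. None of the named genes and lists past the threshold changed sign in these fits. Of the 94 named calls 56 held in all 6 fits without a library, as did 9 of the 13 lists. Deviations from the group means correlated at 0.031, 0.013 and 0.065 between same-numbered WT and cKO libraries, and at -0.054 to 0.023 between the others. These values are small, so they neither pair the libraries nor exclude a pairing. The replicate block gave 1798 genes (1567 shared) and ended the calls of the Leydig list (camera adjusted p = 0.0546) and Vldlr (edgeR adjusted p = 0.0572). Its exact sign-flip p for the scores was 0.25, the smallest possible. The score differences ranged from -0.25 to -0.16 and from -0.88 to -0.80 without 1 library. In the simulated data 48% of changes of 0.5 and 66% of changes of 1 on the log2 scale were called, so genes that did not pass can have changed. Of the edgeR calls there 8.51% had not been planted, so some called genes can be false.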

Other observations

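The lists here and their tests were chosen after the data were seen, and they carry no explanation. Of 73 ribosome biogenesis genes tested, 23 fell, 0 rose and the others did not pass, 64 were fitted below 0, and the median log2 fold change was -0.15 (camera p = 1.1e-10, and p = 0.0439 with an estimated correlation, not adjusted). Mdn1, an assembly factor of the large ribosomal subunit, fell from 325.0 ± 10.3 to 242.6 ± 7.9 CPM (SD, n = 3 each; log2 fold change -0.42, edgeR adjusted p = 0.00035). Utp4 (-0.46), Heatr1 (-0.45), Ddx10 (-0.41) and Nop14 (-0.38) fell as well.

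Of 20 tested markers of the mesothelium, the outer lining of the testis, 5 fell and 0 rose, and the median log2 fold change was -0.50 (camera p = 0.0014, and p = 0.294 with an estimated correlation, not adjusted). In 10 of the 20 the cKO libraries all lay below the WT libraries, against 14.6% of all genes tested and 5% by chance. The genes that fell were Bnc1 (-0.92), Gpm6a (-1.08), which lies in the chromosome 8 segment, Muc16 (-1.08), Msln (-1.24) and Krt7 (-1.47), which the duct epithelium list also holds.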
